A study of Mus musculus with 6 samples.

How the data were processed

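Small RNA was sequenced from extracellular vesicles that osteoblasts shed during apoptosis. Per the labels' protocols, osteoblasts were driven into apoptosis in serum-free medium, the supernatant was cleared of cells and debris by centrifugation, and the vesicles were pelleted by ultracentrifugation. RNA was extracted with Trizol, and small RNA libraries were made with a commercial kit. The series holds 6 libraries: 3 from mice with floxed Sirt6 alleles and no Cre (control) and 3 from Prx1cre;Sirt6f/f mice (knockout), in which Cre driven by the Prx1 enhancer removes Sirt6 in the limb mesenchyme lineage. Groups and replicate numbers were taken from the sample labels. The labels do not say that replicates came from separate animals or cultures, so p-values measure at most the spread between these samples, which may be technical. Those of the main test rest on a spread pooled over entries, as given below, so very small ones do not show tight replicates.

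The authors deposited 1 table of RPM values (reads normalised to the total of each library) with 1712 entries: 1528 carry a mouse miRNA name and 184 carry only a numeric ID with no name or sequence, called unnamed entries here. The mmu- prefix is omitted from miRNA names. Per the submitters' processing notes, fastp and edgeR were used, with their roles and versions not stated; the aligner, the miRNA annotation release and the genome build are not given in the sources used here. Each column of the deposited RPM table sums to 1000000 over all entries, unnamed ones included, so a rise of any abundant entry lowers the RPM of the others. Every RPM value was a whole multiple of 0.5 of the lowest non-zero value of its column, within a tolerance of 0.001 read. The lowest non-zero value then stands for 2 reads and no entry was at 1 read, so the recovered numbers are not complete raw counts. The recovered depth was 1352045 to 1627705 reads in the control libraries and 1608276 to 1838239 reads in the knockout libraries. A level of 3 reads corresponds to 1.63 to 2.22 RPM, depending on the library. Without molecular identifiers, reads are not independent molecules, and depth limits and intervals cover counting error only. For the share of unnamed entries in knockout replicate 3, the 95% Wilson interval was 62.7% to 62.8%.

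Entries with an RPM of at least 1 in at least 3 libraries were tested (1114 of 1712). The main test was limma 3.58.1 in R 4.3.3 with a mean-variance trend on log2(RPM + 1), 2-sided, with Benjamini-Hochberg adjusted p under 0.05. Fold changes are on that scale, which understates changes of low entries. In this fit limma placed the whole weight on the trend (4456 degrees of freedom), so that each entry's own spread between replicates hardly entered its standard error; a robust prior was 1 of the alternatives. Lists of miRNAs, 21 in all, were fixed before the data were examined and tested with camera at a preset correlation of 0.01, with an estimated correlation and fry as alternatives. The total RPM of each list and the composition of the libraries were compared with exact 2-sided permutation tests, whose smallest p for 3 against 3 libraries is 0.1. For 36 hairpins with both arms listed under the same name, each at a mean of at least 10 RPM, limma was run on log2((5p RPM + 1)/(3p RPM + 1)).

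The named entries were chosen by a rule fixed in advance: the 12 largest rises and the 12 largest falls past the threshold with a mean of at least 10 RPM and no overlap between the groups, the 10 most abundant entries, and up to 4 of the most abundant tested members of each list. A selection of these is printed, and other entries are said to be named after their values were seen. Unnamed IDs could not be paired with a name, and few are printed. Hairpin positions are from GENCODE M21 on GRCm38, matched by miRNA name.

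The tests were tried on simulated data with 200 of 1027 entries changed. The changed entries were drawn only from those with a control mean of at least 10 RPM. For the comparison of knockout with control, 52% of 2-fold and 99% of 4-fold changes were recovered, and 4.43% of calls were false. These recovery rates do not cover entries with a lower control mean, for which recovery was not tried. When each simulated library was closed to a fixed total, as RPM values are, 33.2% of calls were false. The shift of an unchanged entry, calculated from the chosen changes and not measured, was -0.69 on the log2 scale. With no simulated change, 0 entries were called by limma. A 2-fold rise of the mesenchymal list was recovered, 0 lists were called by camera with no change, and 100% of 10 hairpins with a 4-fold change of the arm ratio were recovered with 0 false calls. The simulated entries were drawn independently and with the same relative spread, so correlated list members were not tried. In the data the estimated correlation of the mesenchymal list was 0.59. The false calls counted in the simulation may therefore be too few for these data.

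Alternatives were other pseudocounts, filters and scalings, a replicate block, a robust prior and leaving out each library. Rescaling to annotated entries, rescaling to annotated entries outside the list of possible RNA fragments, and limma voom on the recovered reads were added after seeing the data. Count models in edgeR and DESeq2 were not run, because single reads are absent from the recovered numbers. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for the permutation and Fisher tests, and matplotlib 3.10.9 for the figures. Sirt6 is a protein-coding gene, so its removal could not be checked in these small RNA libraries.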

Results

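Small RNA was profiled in extracellular vesicles from apoptotic osteoblasts, the bone-forming cells, of control mice (Sirt6f/f, n = 3 libraries) and of mice lacking the deacetylase Sirt6 in the limb mesenchyme lineage (Prx1cre;Sirt6f/f, n = 3 libraries, called knockout). The comparison asks how the miRNA content of these vesicles differs between the genotypes. The recovered depth was 1352045 to 1838239 reads per library, and 943 to 1115 entries had an RPM above 0. Pearson's r across entries, which are not independent replicates, was 0.9498 to 0.9575 within the control group, 0.9516 to 0.9605 within the knockout group and 0.9296 to 0.9554 between the groups.

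Ordinary annotated miRNAs took a smaller share of the listed reads in the knockout than in the control libraries. Fragment-like and unnamed entries took a larger share. Shares of reads do not give the amounts of RNA in the vesicles. The unnamed entries carry no miRNA name, and the kind of RNA they stand for is not given in the sources used here. A list of 11 annotated entries was set apart in advance as possible ribosomal or transfer RNA fragments and is called fragment-like here, although that origin was not established in these data. Annotated miRNAs outside it took 49.3% ± 2.79 of reads in the control group and 35.9% ± 5.46 in the knockout group (mean ± SD, n = 3 each). The fragment-like entries, among them miR-6236 and miR-6239, took 3.08% ± 1.07 and 7.49% ± 0.534. Unnamed entries took 47.6% ± 3.85 and 56.6% ± 5.37. For each of these shares the groups did not overlap (exact permutation p = 0.1, the smallest that 3 against 3 libraries allow). The share of the 10 most abundant entries of each library was 46.1% ± 2.04 in the control and 48.4% ± 6.37 in the knockout group (exact permutation p = 0.8). Knockout replicate 3 had the lowest share of ordinary annotated miRNAs; without it the difference between the groups was -10.4 percentage points, against -13.4 with all libraries, and that of the unnamed entries was 5.96 points, against 9.03.

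**Figure D1:**
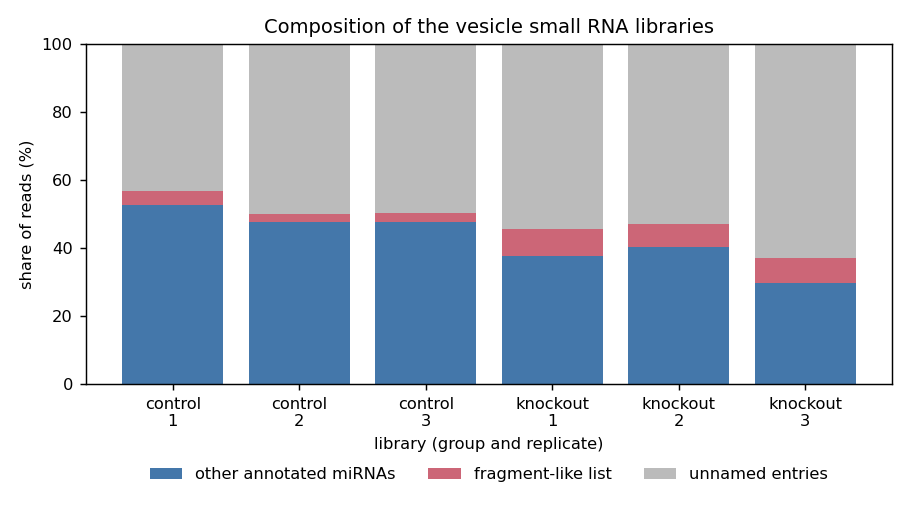
Share of reads (percent, y axis) taken by ordinary annotated miRNAs, by fragment-like entries and by unnamed entries in each of the 6 libraries (x axis), 1 stacked bar per library. The ordinary annotated share lay between 47.7% and 52.6% in the control libraries and between 29.8% and 40.3% in the knockout libraries.

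Among single entries, the rises in the knockout vesicles included miR-7087-3p and members of known clusters, and the falls included miR-29a-3p and miR-22-3p. miR-7087-3p rose from 158 ± 61.8 to 843 ± 572 RPM (log2 fold change 2.29 ± 0.29 SE, limma adjusted p = 7.75e-12), and miR-494-3p, from the imprinted Dlk1-Dio3 locus, rose from 599 ± 192 to 2211 ± 645 RPM (1.89 ± 0.29, limma adjusted p = 1.93e-08). miR-542-3p rose from 8171 ± 1369 to 23029 ± 9612 RPM (1.43 ± 0.33, limma adjusted p = 0.00103). miR-29a-3p, which targets collagen mRNAs, fell from 3361 ± 609 to 1601 ± 559 RPM (-1.12 ± 0.29, limma adjusted p = 0.00664), and miR-22-3p fell from 4541 ± 600 to 2454 ± 846 RPM (-0.95 ± 0.30, limma adjusted p = 0.0378). In all, 24 entries were higher and 30 lower among 1114 tested (limma, adjusted p under 0.05). Of the annotated miRNAs, 16 of 950 were higher and 29 lower, and of the unnamed entries, 8 of 164 were higher and 1 lower. The groups did not overlap for 285 entries (25.6%, against 10% by chance). Of these, 190 were among the 354 entries with a mean of at least 10 RPM (53.7%). Entries share the total of a library and are not independent, so the excess over 10% does not tell how many entries changed.

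Other rises past the threshold included those of miR-6942-3p (3.24), miR-6715-3p (2.21), miR-8099 (2.07), miR-6236 (1.96), miR-668-3p (1.62) and miR-6239 (1.39), all as log2 fold changes. miR-6942-3p had only 1.61 ± 1.83 RPM in the control group, close to the level of 3 reads. miR-6942-3p lies within an intron of Zkscan3 (GRCm38 chromosome 13, 21396578 to 21396638), miR-7087-3p within an intron of Sidt2 (chromosome 9, 45939521 to 45939590) and miR-6715-3p within an exon of Tectb (chromosome 19, 55192678 to 55192734). The unnamed entry 4_57299 rose from 15886 ± 3837 to 69097 ± 21112 RPM (2.10 ± 0.36, limma adjusted p = 7.28e-07). The unnamed entry 3_51029 rose from 41595 ± 1659 to 102090 ± 47588 RPM (1.19 ± 0.38, limma adjusted p = 0.0426). It was the most abundant by the mean over all libraries, though the unnamed entry 4_54497 was higher in the control group (83788 ± 3398 RPM). The call of 3_51029 was lost in 5 of 6 settings with a library left out.

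Among entries past the threshold with a mean of at least 10 RPM and no overlap between the groups, the largest falls were those of miR-503-5p (-1.50), miR-3968 (-1.49), miR-144-3p (-1.47), miR-127-3p (-1.46), miR-122b-3p (-1.39), miR-339-5p (-1.30), miR-149-5p (-1.15), miR-484 (-1.14), miR-107-3p (-1.13), miR-29a-3p (-1.12), miR-450a-5p (-1.09) and miR-92b-3p (-1.08), with limma adjusted p from 0.000329 for miR-503-5p to 0.0456 for miR-339-5p and miR-92b-3p. The hairpins of miR-503-5p and miR-542-3p lie near each other on chromosome X (53053984 to 53054054 and 53049403 to 53049487, both intergenic in the annotation), yet miR-503-5p fell and miR-542-3p rose. The only lower unnamed entry was 2_48053 (-0.99), named here after its value was seen. The most abundant annotated miRNAs did not pass the threshold: miR-99a-5p (-0.76, limma adjusted p = 0.212), miR-143-3p (-0.94, limma adjusted p = 0.0858) and miR-26a-5p (-0.78, limma adjusted p = 0.185).

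The falls depended on what the reads were scaled to. Over the 264 ordinary annotated miRNAs with a mean of at least 10 RPM, the median log2 fold change was -0.60 and 213 lay below 0; over all entries the median was -0.27. When the libraries were rescaled to ordinary annotated miRNAs, a choice made after seeing the data, the median over all entries was 0.07 (-0.08 with scaling to all annotated entries or median centring and -0.05 with quantile normalization), 34 entries were higher and 1, miR-3968, was lower. The counts of higher and lower entries were 27 and 5 with scaling to all annotated entries, 32 and 8 with median centring, and 32 and 16 with quantile normalization. Without control replicate 3, limma called 0 entries in either direction (53 higher and 84 lower at an unadjusted p under 0.05), without control replicate 2 it called 6 higher and 0 lower (62 and 128; median -1.13 for the 30 lower entries), and without control replicate 1 it called 18 and 3. Without control replicate 3 the entries called with all libraries kept a median log2 fold change of 1.499 (higher, against 1.548) and -1.07 (lower, against -1.05), while the median SE of the lower ones went from 0.31 to 0.40. Without knockout replicates 1, 2 and 3 limma called 18 and 18, 14 and 6, and 26 and 15. The calls of miR-22-3p, miR-107-3p, miR-339-5p, miR-467a-5p and miR-92b-3p were lost whichever library was left out.

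**Figure D2:**
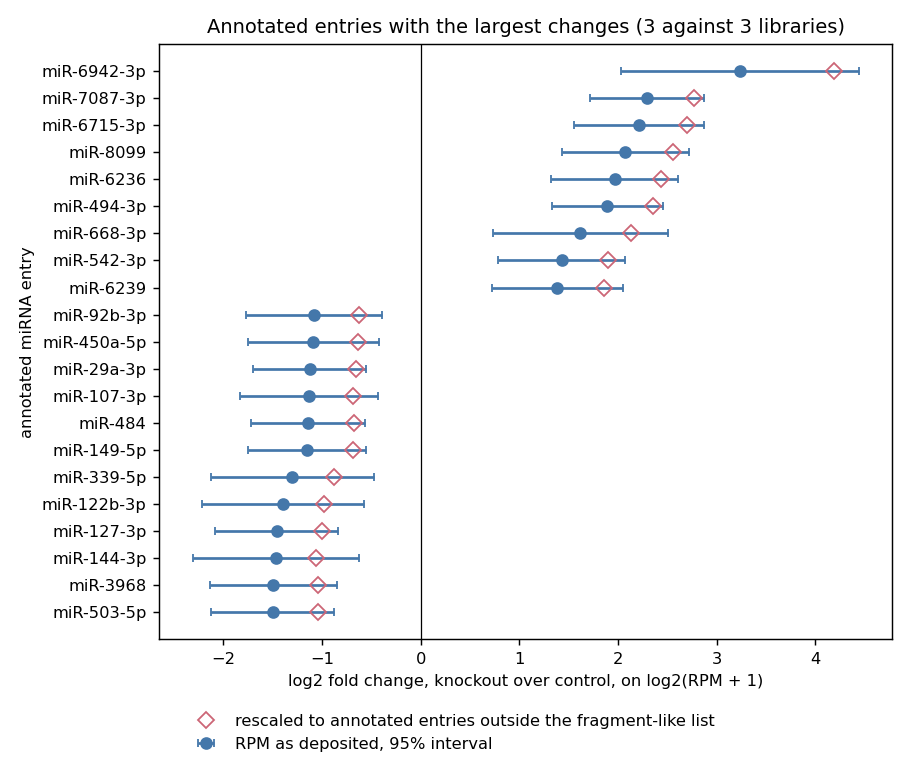
Log2 fold change (knockout over control, x axis, on log2(RPM + 1)) of the annotated entries (y axis) with the largest changes past the threshold; filled circles with 95% intervals are RPM as deposited and open diamonds are values after rescaling to ordinary annotated miRNAs. The rises, such as miR-494-3p (1.89 and 2.36), moved away from 0 with the rescaling and the falls, such as miR-29a-3p (-1.12 and -0.66), moved towards it. Both shifts follow from the rescaling, which raised values in the knockout libraries relative to the control ones.

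Lists of miRNAs fixed before the data were examined were then compared. Mesenchymal miRNAs, which mark the lineage of the donor cells, were lower as a list: 37 of 41 tested members lay below 0, with a median of -0.72. The camera adjusted p was 2.95e-06, and the adjusted p = 0.603 with an estimated correlation. Their total went from 281780 ± 20951 to 179310 ± 49940 RPM (ratio 0.636, exact permutation p = 0.1). Abundant miRNAs were lower in general, so these values do not single out the mesenchymal list. Ordinary annotated miRNAs with a mean of at least 10 RPM had a median of -0.60, with 80.7% below 0. Those with a mean of at least 1000 RPM had a median of -0.67, with 82.6% below 0. Camera set the list against all tested entries, whose median was -0.27. Of the 41 members, 6 were lower and 0 higher by limma, and 16 were lower when adjusted over the list alone. miR-214-3p, named after its value was seen, fell by 1.05 on the log2 scale (limma adjusted p = 0.0118), and miR-22-3p also passed, though without knockout replicate 3 these values were -0.63 and -0.62, and the call of miR-214-3p was lost in 4 of 6 settings with a library left out; miR-125b-5p (-0.79, limma adjusted p = 0.179) and miR-199a-5p (-0.68, limma adjusted p = 0.2495) did not.

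For each of the next 5 lists the camera adjusted p = 0.603 with an estimated correlation. Their medians stand beside -0.60 for ordinary annotated miRNAs with a mean of at least 10 RPM. Of 38 tested miRNAs with roles in osteoblast differentiation, 5 were lower and 0 higher, among them miR-29a-3p, miR-22-3p and miR-214-3p, and 9 were lower when adjusted over the list alone; 11 of the 38 are also on the mesenchymal list. The median was -0.65 (camera adjusted p = 0.00276). Of the p53 and senescence list, 5 of 28 were lower, including miR-107-3p and miR-29a-3p, and 8 when adjusted over the list alone (median -0.47, camera adjusted p = 0.0239). The call of this list was lost without knockout replicate 3 (camera adjusted p = 0.158) and without control replicate 3 (camera adjusted p = 0.102). It was also lost with scaling to all annotated entries (camera adjusted p = 0.0848). miR-34c-5p, a p53 target, had a value of -0.39 (limma adjusted p = 0.529), which turned to 0.07 after rescaling to ordinary annotated miRNAs. Of the inflammation list, 1 of 19 was lower and 3 when adjusted over the list alone (median -0.70, camera adjusted p = 0.0239). The inflammation call was lost without control replicate 2 (camera adjusted p = 0.0665). Its member miR-21a-5p had -0.24 (limma adjusted p = 0.747), which turned to 0.23 after the same rescaling, and miR-146b-5p had -0.47. The 18 tested let-7 family members, which restrain growth genes, had a median of -0.68 with 0 past the threshold in either adjustment (camera adjusted p = 0.0182); let-7i-5p had -0.71 and let-7b-5p -0.82. The 10 members of the miR-23-27-24 clusters all lay below 0 with 0 past the threshold in either adjustment (median -0.59, camera adjusted p = 0.0355), as for miR-27b-3p (-0.77). The call of these clusters was lost without control replicate 1 (camera adjusted p = 0.0523) and without control replicate 2 (camera adjusted p = 0.107).

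Among markers of other cell types, camera called the blood cell and endothelial lists lower, with an adjusted p = 0.603 for each with an estimated correlation, and called no other. Of 11 blood cell miRNAs, 2 were lower, miR-486b-5p (-1.03, limma adjusted p = 0.0172) and miR-144-3p, and 5 when adjusted over the list alone (median -0.85, camera adjusted p = 0.0239). The blood cell call was lost without knockout replicate 3 (camera adjusted p = 0.0783) and without control replicate 2 (camera adjusted p = 0.0665). The endothelial call held whichever library was left out. The erythroid miR-451a had -0.85 (limma adjusted p = 0.141). All 4 tested endothelial entries, both arms of miR-126a and miR-126b, lay below 0 (median -1.29, camera adjusted p = 0.0239), 0 passed over all entries and 3 when adjusted over the list alone. The hairpins of miR-126a and miR-126b lie on opposite strands of the same locus (chromosome 2, 26591357 to 26591429 and 26591363 to 26591420). The 4 entries are therefore not independent members. Endothelial miRNAs were rare, at 93.3 ± 10.4 RPM in total in the control and 40.3 ± 15.0 RPM in the knockout group. The epithelial (6 tested, median 0.03, camera adjusted p = 0.476), muscle (5 tested, median 0.22, camera adjusted p = 0.476), neural (3 tested, median -0.70, camera adjusted p = 0.319) and liver and gut lists (6 tested, camera adjusted p = 0.789) had 0 members past the limma threshold, over all entries or over the list alone. The liver and gut list had a median of 0.06 and a mean of -0.20. Single members were miR-200c-3p (0.46, and 0.27 without control replicate 2), miR-206-3p (-0.56), miR-128-3p (-1.10) and miR-192-5p (-0.59); without knockout replicate 3 the last 3 had -0.37, -0.54 and -0.26.

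The imprinted Dlk1-Dio3 cluster on chromosome 12 split in direction. Of 44 tested members, 4 were higher and 1 was lower, over all entries and over the list alone. miR-494-3p and miR-668-3p rose, as did miR-136-5p (from 1.95 ± 1.69 to 10.9 ± 4.32 RPM) and miR-487b-5p (listed at 0 in all control libraries and at 9.23 ± 7.45 RPM in the knockout group), the latter pair named after their values were seen. The partner arm miR-494-5p had 0.89 ± 0.78 RPM in the control and 0.36 ± 0.63 RPM in the knockout group. No partner arm of miR-668-3p was listed. For miR-494-3p and miR-668-3p, reads that do not come from a processed hairpin therefore stay possible. Of 6 settings with a library left out, the call of miR-494-3p was lost in 1, miR-487b-5p in 3, miR-668-3p in 4 and miR-136-5p in 5. After rescaling to ordinary annotated miRNAs, miR-136-5p no longer passed (limma adjusted p = 0.0812). miR-127-3p fell from 201 ± 39.7 to 78.5 ± 36.3 RPM. The median of the cluster was -0.30, which turned to 0.06 after rescaling to ordinary annotated miRNAs, while camera pointed upward (adjusted p = 0.476). The total, most of it miR-494-3p in both groups, went from 1103 ± 230 to 2542 ± 572 RPM (ratio 2.31, exact permutation p = 0.1, Benjamini-Hochberg adjusted p = 0.131 over 21 list totals). In the repeat-rich Sfmbt2 cluster, whose members can share reads, 1 of 26 was lower, miR-467a-5p (-1.07, limma adjusted p = 0.0330), and 1 was higher and 3 lower when adjusted over the list alone; miR-297b-5p had 0.82 (limma adjusted p = 0.0706), and 0.42 without knockout replicate 3. Its median was -0.61 (camera adjusted p = 0.319).

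Of the 11 fragment-like entries, 3 rose and 1 fell. miR-6239 rose from 12861 ± 4328 to 32487 ± 1751 RPM, miR-6236 from 7596 ± 3238 to 28386 ± 5045 RPM, and miR-6238 by 1.30 on the log2 scale, whereas miR-3968 fell and miR-6240 had 0.50 (limma adjusted p = 0.378), a value between 0.19 without knockout replicate 1 and 0.9999 without knockout replicate 3, where it passed (limma adjusted p = 0.0396). Adjusted over the list alone, 3 were higher and 2 lower. The median of the list was 0.08 (camera adjusted p = 0.0716).

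Other families had few calls. Of 4 miR-29 members, 1 was lower, miR-29a-3p, and 2 when adjusted over the list alone, with miR-29b-3p at -1.15 (limma adjusted p = 0.0609). The family total went from 3418 ± 618 to 1633 ± 574 RPM (ratio 0.478, exact permutation p = 0.1). None of the miR-30 (11 tested, median -0.53), miR-17 polycistron and paralog (16 tested, median -0.46), miR-15-16 (13 tested, median -0.41), miR-181 (6 tested, median -0.77) or miR-148-152 members (6 tested, median -0.48) passed the limma threshold over all entries. Adjusted over the list alone, 1, 2, 1, 1 and 2 of them were lower, respectively. Single values were -0.43 for miR-30a-5p, which turned to 0.04 after rescaling to ordinary annotated miRNAs, -0.84 for miR-92a-3p, -0.86 for miR-25-3p, -0.48 for miR-16-5p, -0.86 for miR-181a-5p and -0.82 for miR-148a-3p. The camera adjusted p was 0.264 for the miR-29, 0.119 for the miR-30, 0.497 for the miR-17 polycistron and paralog, 0.304 for the miR-15-16, 0.113 for the miR-181 and 0.212 for the miR-148-152 list.

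Knockout replicate 3 carried a large part of many of these values. Without it, 20 of 58 named entries moved by over 1.5 times, 19 of them towards 0. Besides those given above, the values without it were -0.59 for miR-29b-3p, -0.56 for 2_48053 (no longer past the threshold, limma adjusted p = 0.206), -0.54 for miR-181a-5p, -0.53 for miR-148a-3p, -0.51 for miR-143-3p, -0.45 for miR-25-3p and miR-27b-3p, -0.43 for miR-199a-5p, -0.41 for let-7i-5p, -0.28 for miR-16-5p, -0.25 for miR-30a-5p, -0.19 for miR-34c-5p and -0.07 for miR-21a-5p, which had -0.41 without knockout replicate 2.

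Across the 21 lists, camera called 8, all downward, at a preset correlation. It called 0 with an estimated correlation (1 at an unadjusted p under 0.05), and fry called 0 (4 at an unadjusted p under 0.05, smallest adjusted p = 0.0757). Without control replicate 2, camera called 5 lists. Among entries with an RPM of at least 10 in 3 libraries, it called 1 of 17 lists. After rescaling to ordinary annotated miRNAs, camera called the mesenchymal (adjusted p = 0.00687) and osteoblast differentiation lists (adjusted p = 0.0175) downward. It also called the endothelial list, whose entries share a locus, downward (camera adjusted p = 0.0175) and the fragment-like list upward (camera adjusted p = 0.0175). These 4 calls used the preset correlation and set each list against all tested entries, whose median was 0.07 on this scale. They do not set the mesenchymal and osteoblast differentiation lists apart from other abundant miRNAs. An estimated correlation and fry were not tried on the rescaled values.

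**Figure D3:**
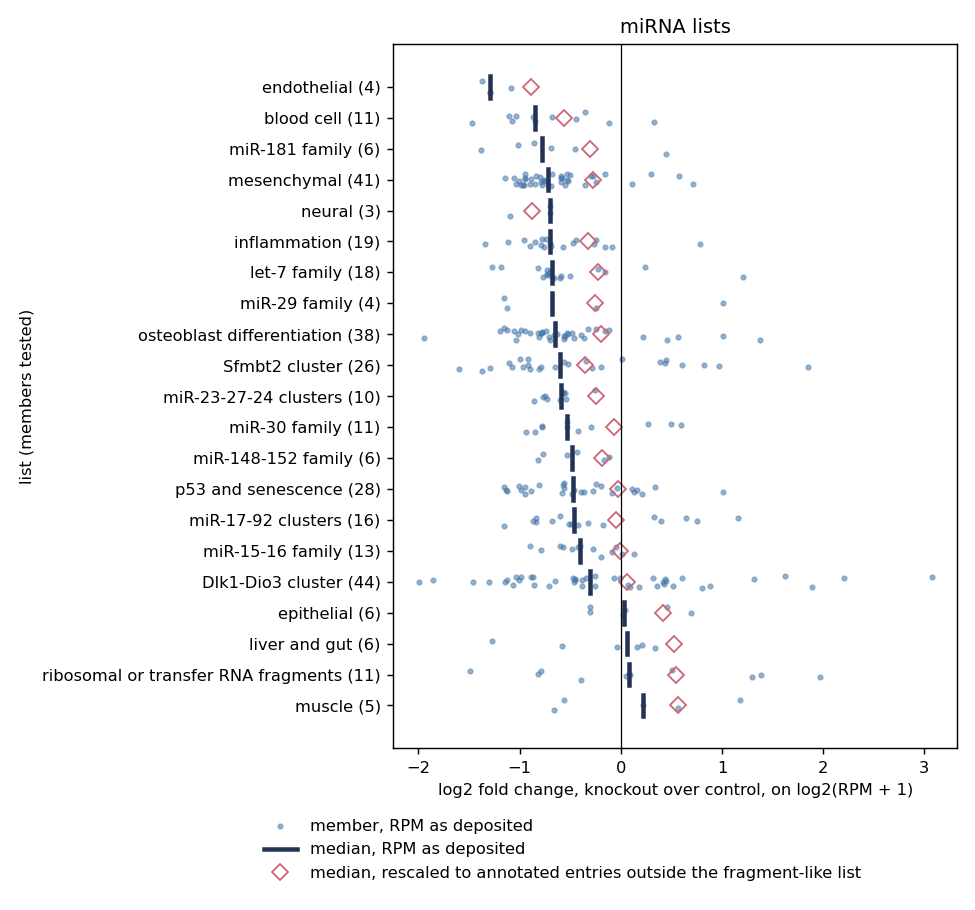
Log2 fold changes (knockout over control, x axis, on log2(RPM + 1)) of the tested members of each of the 21 lists (y axis, members tested in brackets); points are members, bars the median of RPM as deposited and open diamonds the median after rescaling to ordinary annotated miRNAs. The mesenchymal median went from -0.72 to -0.28 and the Dlk1-Dio3 median from -0.30 to 0.06 with the rescaling.

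The ratio of the arms of a hairpin does not depend on the scaling of a library beyond the pseudocount. Of 36 hairpins tested, 2 shifted towards the 5p arm in the knockout vesicles and 0 towards the 3p arm (limma; 5 at an unadjusted p under 0.05). For miR-107, within an intron of Pank1, the log2 ratio of the 5p to the 3p arm went from 0.33 ± 0.16 to 1.79 ± 0.46 (difference 1.47 ± 0.30 SE, limma adjusted p = 0.0126). For miR-144 it went from -1.56 ± 0.20 to -0.21 ± 0.61 (1.35 ± 0.33, limma adjusted p = 0.0241). For miR-145a, named after its value was seen, the difference was 1.001 ± 0.292 (limma adjusted p = 0.0561). Without control replicate 2, knockout replicate 2 or knockout replicate 3, limma called 0 hairpins (5, 4 and 4 at an unadjusted p under 0.05), where the difference was 1.51, 1.20 and 1.61 for miR-107 and 1.28, 1.43 and 1.02 for miR-144. Without knockout replicate 1 it called 7.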

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

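Rescaling to annotated entries, with or without the fragment-like ones, and voom were chosen after seeing the data; the other alternatives were fixed before. Against 24 higher and 30 lower entries, a pseudocount of 0.1 gave 9 and 1. The number of lower entries was 15 with no filter on low values, 60 with an RPM of at least 10 in 3 libraries (358 entries tested), 8 with median centring, 16 with quantile normalization, 17 with a robust prior variance, 5 with scaling to annotated entries and 1 with scaling to annotated entries outside the fragment list, while the number of higher entries stayed between 21 and 34. The centring, the quantile normalization and both scalings moved the median over all entries upward, from -0.27 to between -0.08 and 0.07. They favour rises, so the rises kept under them do not test whether the rises depend on scaling. Leaving out the 3 most abundant entries gave 27 and 28, a pseudocount of 5 gave 23 and 28, and voom on recovered reads 26 and 26. The replicate numbers did not pair the libraries (correlations of 0.0055, -0.024 and 0.011 for the same numbers), and the replicate block gave 19 and 11, with 8 lists and 2 hairpins. Against 8 lists called, 1 of 17 was called with an RPM of at least 10, 4 with scaling to annotated entries outside the fragment list, and 0 with an estimated correlation or with fry. Against 2 hairpins, 1 was called with a pseudocount of 0.1 and with quantile normalization, and 4 with a pseudocount of 5. With a mean of at least 100 RPM per arm, 1 of 7 was called, miR-145a; miR-107 and miR-144 were below that level and so were not retested. Leaving out single libraries gave 0 to 26 higher entries, 0 to 18 lower entries, 5 to 9 lists and 0 to 7 hairpins; 0 higher entries were called without control replicate 3, 0 lower ones without control replicate 2 or 3, and the highest counts came without knockout replicate 3 (higher entries) or knockout replicate 1 (the others).

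Direction reversed for miR-21a-5p with scaling to annotated entries (0.036) and for miR-21a-5p (0.23), miR-30a-5p (0.040) and miR-34c-5p (0.075) with scaling to annotated entries outside the fragment list, none of them past the threshold before or after. Among 1040 values of the named entries under all alternatives, 819 kept their direction and side of the threshold, 200 no longer passed it, 17 newly passed it and 4 reversed. The 819 include entries that had not passed in the main fit and so had no call to lose. With a library left out, 105 of 348 values no longer passed. Without control replicate 3 this held for 31 of 58, where 27 were the same and no entry passed. Scaling to annotated entries lowers the number of falls by construction, since it raises every value in the knockout libraries relative to the control ones, and with the fragment-like entries left out it also lowered the degrees of freedom from 4456 to 12.2; leaving out a library removes samples; for the pseudocount, the filters, the centring and the robust prior the cause was not tested. Count models in edgeR and DESeq2 were not run, because single reads are absent from the recovered numbers. Entries near 3 reads, such as miR-6942-3p in the control libraries, are limited by depth.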

Other observations

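The rescaling, the partner arm test with its matching of names, the degrees of freedom, the leaving out of transcripts of an entry's own hairpin gene and the ratio within the cluster were chosen after the result was seen. A pair of neighbouring hairpins and an imprinted locus stood out for members that moved apart within the same libraries; the pairs were picked for that, so their ratios describe the pattern and do not test it. The log2 ratio of miR-542-3p to miR-503-5p was 5.29 ± 0.41 in the control and 8.21 ± 1.34 in the knockout group (mean ± SD, n = 3 each), and that of miR-494-3p to miR-127-3p was 1.54 ± 0.55 and 4.89 ± 1.17.

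The fall of annotated miRNAs is open to a technical explanation. Reads taken by unnamed and fragment-like entries lower all others on a per-million scale, and after rescaling to annotated entries outside the fragment list 1 of 29 lower annotated calls still passed; their median went from -1.05 (median SE 0.31) to -0.59 (median SE 0.23), with all 29 still below 0. Smaller estimates and fewer degrees of freedom (12.2, against 4456 as deposited) could each end calls. At the rescaled SEs and degrees of freedom, 29 of the 29 passed with the deposited estimates and 1 with the rescaled ones. In that setting the smaller estimates ended the calls. With the rescaled estimates and SEs at 4456, 9 passed. At the deposited SEs, 3 passed with the rescaled estimates at 4456 and 0 with the deposited estimates at 12.2, so there either change ended most calls. The same value would follow from a true loss of miRNA per vesicle, since relative values cannot separate these, and an effect of the genotype stays open and untested. A single deviating library as the whole cause is argued against. Without knockout replicate 3 the median of the 264 abundant annotated miRNAs was -0.39 (bootstrap 95% interval over entries -0.43 to -0.33). That interval resamples entries of the same libraries, so it does not cover the spread between libraries. Against the control mean, the medians of knockout replicates 1 and 2 were -0.39 and -0.33, while knockout replicate 3 lay at -1.07. Those of control replicates 1, 2 and 3 were 0.10, -0.07 and -0.03.

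The annotated entries that rose could hold reads of other RNAs. Of the 8 higher entries that were the more abundant named arm of a hairpin and had a mean of at least 10 RPM, 7 had a partner arm under 1 RPM or not listed, gene copies of a name counted together, against 63 of 180 other such entries (Fisher's exact p = 0.00453; with at least 100 RPM, 5 of 6 against 24 of 94, Fisher's exact p = 0.00747), consistent with reads that do not come from a processed hairpin. Of the 13 higher annotated entries with a mean of at least 10 RPM, fragment-like ones included, 0 shared a run of 18 bases with a searched non-miRNA RNA, with transcripts of an entry's own hairpin gene left out, against 14 of 251 other entries (Fisher's exact p = 1). That comparison met the bound set in advance against reads of other abundant RNAs, but it decides little: the searched set turned out to hold 0 cytosolic transfer RNAs and no ribosomal RNA longer than 1849 bases, which was noticed after the result. An effect of the genotype on these entries stays open and untested.

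For miR-542-3p against miR-503-5p, the log2 ratio within a library differed by 2.93 ± 0.81 (SE) between the groups (exact permutation p = 0.1). Scaling cancels in such a ratio, apart from the pseudocount, so it would not by itself move the 2 entries apart. The pair was picked because its members moved apart, so the ratio restates that pattern and is no test of scaling. Reads of another RNA counted in miR-542-3p cannot be told apart from a change of the miRNA, because the partner arm miR-542-5p was at 1.56 ± 1.36 RPM in the control group and listed at 0 in the knockout group, too few reads to follow. A change of the miRNA with the genotype is a hypothesis that stays open.

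Of the 10 splits of the 6 libraries into equal groups, 1, the real one, gave as many entries (54, against at most 0 in the others), 1 as many hairpins (2, against 0) and 1 as many lists (8, against 3). With 10 splits a share under 0.05 cannot be reached.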
